A study of Brassica napus with 23 samples.

How the data were processed

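Total RNA of Brassica napus (oilseed rape, an allotetraploid crop with an A and a C subgenome) was sequenced in 23 libraries. Per the labels, plants grew for 14 days and were treated 7 days after planting. The labels give these values for the 24 h harvest too, although 24 h after that treatment falls before day 14. The age of the plants at the 24 h harvest is therefore uncertain. The treatment was either LB broth, which served as the negative control, or 15 mL of a culture of Pseudomonas chlororaphis PA23, a bacterial strain used as a biocontrol agent. Shoots and roots were harvested 24 h and 7 d after treatment. Tissue, treatment and harvest make 8 groups, of 3 libraries each except the root control group at 24 h, in which 2 libraries carry the replicate numbers 2 and 3. A replicate 1 of that group is not analysed here. The labels also carry a pair of numbers in brackets whose meaning is not given in the sources used here. Its second number equals the replicate number in all but 2 libraries: shoot PA23 7 d replicate 1 is labelled 2-3 and root control 24 h replicate 2 is labelled 1-1. Replicate numbers are those of the titles. Nothing in the labels states whether replicates of a group came from separate plants, so the p-values measure only the spread between these libraries, which may be partly technical.

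The deposited values are whole-number counts per gene for 101040 gene IDs, not scaled for depth. Per the submitters' processing notes, HISAT2 aligned the reads and DESeq2 was also used; no version of either is given. The genome build, the annotation, the strand setting and the counting tool are not given in the sources used here. In the deposited table the length of each of the 101040 genes equals its end minus its start plus 1, so introns, where present, lie inside the counted span. Low counts were mostly even. Among counts from 1 to 10, a median of 30.1% were odd in 22 libraries (range 18.9% to 33.6%), as when both mates of a read pair are counted, and 57.6% were odd in root PA23 7 d replicate 1. A count is therefore not everywhere an independent molecule. Intervals from counts treat each count as independent and leave out the spread between libraries. Where both mates were counted they are too narrow even for counting error. How reads shared by near-identical A and C copies of a gene were assigned is not given in the sources used here, so the split of a signal between such copies is uncertain.

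Gene names could not be paired with most IDs. Of the 101040 IDs, 3347 (3.31%) matched a symbol of the RefSeq table of the Da-Ae assembly when case was ignored, and 2 of those carried another name. The 42 gene lists written before the data were examined, which rest on gene names and descriptions, could therefore not be filled and none was tested. Genes are given by the IDs of the deposited table with its coordinates, whose build is not given in the sources used here. At most 2 genes that rose and 2 that fell are printed per comparison. The rule, fixed at the same time as those lists, took those with the largest log2 fold change among genes past the threshold with a mean of at least 1 on the log2 CPM scale, and, for contrasts of 2 groups, no overlap between the groups. Single calls are also named where a comparison had few, and these are said to have been chosen after their values were seen where the rule did not name them.

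Depth ranged from 0.622 to 721 M counts (M, mega) per library (median 45.8 M), a 1160-fold range. In 6 libraries, each in a different group, the total was under 2 M; the other 17 held 16.8 M or more. At 1 M counts a gene at 1 CPM has 1 count, so a low gene in these 6 libraries carries almost no information of its own.

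The counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, libraries were scaled by TMM, and the robust quasi-likelihood test was applied with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. One fit per tissue held its 4 groups, so that they shared one estimate of the spread. A joint fit of all 23 libraries served for differences between tissues. The 10 contrasts were PA23 against control in each tissue at each harvest, the difference of these effects between harvests and between tissues, and 7 d against 24 h in the controls. The standard error of a log2 fold change was taken as its size divided by the square root of F. CPM values are counts per mega TMM-scaled counts, given as mean ± SD.

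Gene lists that need no names were made from the control libraries. For each harvest, the 200 genes with the largest shoot-over-root log2 fold change, among genes past the threshold with at least 3 on the log2 CPM scale in shoot, were called shoot-preferred, and root-preferred genes were chosen likewise. Lists from one harvest were tested at the other, so that no control library both chose and tested a list. These lists were made after the data were examined and are not pathways. They were tested with camera in limma 3.58.1, with the preset correlation of 0.01 and with an estimated correlation, and with fry; p-values were adjusted over the 6 list tests. The level of a list in a library is its summed CPM as a percentage of the mean of the deeper control libraries of that tissue at the other harvest.

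The test was checked on simulated counts with the real means and library sizes, each library drawn independently. Changed genes were drawn only from genes above a minimum CPM, so recovery of low genes was not checked. The simulations held no closely similar pairs, no counting of both mates and no library between the harvests. Their recovery and false calls may therefore not carry over to the real counts. Of 100 genes changed 2-fold and 100 changed 4-fold, edgeR recovered 16% and 80% in shoot at 24 h and 18% and 85% in shoot at 7 d (55525 genes), and 42% and 92% in root at 24 h and 41% and 90% in root at 7 d (62346 genes). False calls were 4.95%, 2.83%, 4.96% and 9.93% of the calls, in that order (5, 3, 7 and 15 genes). At 7 d a further set of genes was raised slightly with PA23, and calls among them were not counted as false. These simulations used trended dispersions and were added after a first version with a dispersion per gene had been seen. That version gave false calls of 18.2% and 18% in shoot (55542 genes) and 17.5% and 8.26% in root (62399 genes), with 14% and 76%, 15% and 75%, 30% and 88%, and 23% and 85% of the changed genes recovered. The share of false calls exceeded the nominal 5% in root at 7 d in both versions and in the other comparisons in the version with a dispersion per gene. Each share rests on a single simulated data set, so its distance from 5% is uncertain.

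Alternatives fixed at that time were RLE size factors, DESeq2 1.42.0, limma-voom with sample weights, no filter, a filter of 10 counts in 3 libraries, each library left out in turn, a replicate block, a fit of only the groups compared, and the sequencing run (1514 or 1522) as a covariate, alone or with the block. The 12 shoot libraries all carried run 1514; of the root libraries, 4 carried run 1514 and 7 run 1522. Alternatives chosen after seeing the data left out the 6 libraries under 2 M counts, summed very similar libraries, halved the counts, or kept genes with an average log2 CPM of 5 or more; the alternatives of the gene lists and of the correlation between effects were also chosen then. Several other fits, filters and library sets had been looked at before these were chosen.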

Results

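The deposited counts cover shoots and roots of Brassica napus treated with LB broth (control) or with the bacterium Pseudomonas chlororaphis PA23 and harvested 24 h or 7 d later. Each of the 8 groups held 3 libraries, except root controls at 24 h with 2. Tissue was the main division among the libraries: over 61038 genes, Spearman correlations between libraries of 16.8 M counts or more were 0.94 to 0.99 within a tissue and 0.51 to 0.58 between tissues. Shoot and root controls differed in 33318 of 68002 genes at 24 h and in 36722 at 7 d (edgeR, adjusted p under 0.05). Depth was uneven, from 0.622 to 721 M counts (M, mega), and 6 libraries in 6 groups held under 2 M. Within a tissue, pairs with at least one of those 6 libraries correlated at 0.76 to 0.93.

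**Figure D1:**
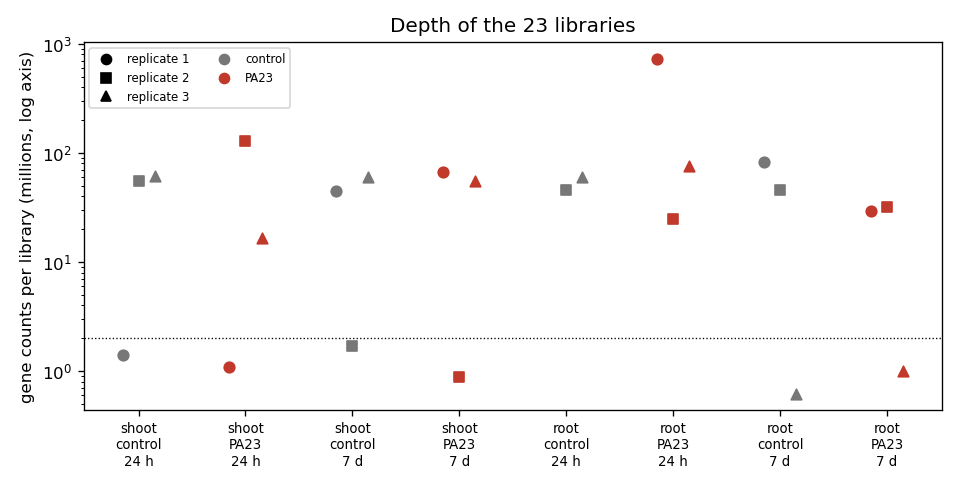
Gene counts per library in mega counts (M) on a log axis, by group, with the marker shape giving the replicate number and the colour the treatment. The dotted line marks 2 M counts; 6 libraries lie below it, and root PA23 24 h replicate 1 is the deepest at 721 M.

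PA23-treated and control roots at 24 h differed in 170 of 63551 genes, 93 higher and 77 lower with PA23 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05; 3 against 2 libraries). The change was at least 2-fold in 90 of the higher and 71 of the lower genes. BnaC03g02770D (chromosome C03, 1375065 to 1376179) rose from 0.74 ± 0.078 CPM in controls (SD, n = 2) to 17 ± 5.73 CPM with PA23 (SD, n = 3), a log2 fold change of 4.52 (SE 0.66, edgeR adjusted p = 0.0282). BnaA08g22090D (A08, 16171074 to 16171990) rose from 0.684 ± 0.532 to 13.6 ± 3.14 CPM (log2 fold change 4.34, SE 0.71, edgeR adjusted p = 0.0301). BnaC06g37480D (C06, 35496609 to 35497118) fell from 5.09 ± 1.58 to 0.582 ± 0.107 CPM (log2 fold change -3.12, SE 0.48, edgeR adjusted p = 0.0124). BnaA03g38440D (A03, 19109547 to 19113476) fell from 13.4 ± 9.72 to 1.65 ± 0.62 CPM (log2 fold change -3.07, SE 0.43, edgeR adjusted p = 0.00799). Called genes made up 0.269% of the tested A genes and 0.265% of the tested C genes (Fisher's exact test, two-sided, p = 0.939, adjusted p = 1 over 8 contrasts). The odds ratio of A against C was 1.01, but 0.55 without PA23 replicate 2 (Fisher's exact p = 0.274) and 0.582 with the 3 closest pairs of libraries summed (0.239), neither past the threshold. The number of called genes was 714 with DESeq2, 4755 with limma-voom, 5666 when only these 5 libraries were fitted, 286 without the libraries under 2 M counts, 259 with no filter and 126 with the sequencing run as a covariate. It was 880 with all counts halved and 4316 with DESeq2 without the libraries under 2 M counts. A replicate block, alone or with the run, brought it below 170, to values given with the processing alternatives below. With the 3 closest pairs of replicate libraries summed it was 26. PA23 replicates 2 and 3 are one of those pairs, with a coefficient of variation of 5.22% between them, against 13.1% to 32.4% in replicate pairs outside the 3. In that fit BnaC03g02770D, BnaA08g22090D and BnaC06g37480D missed the threshold (edgeR adjusted p = 0.0991, 0.1 and 0.0753). The count was 15 without PA23 replicate 3, 21 without PA23 replicate 2, 28 without control replicate 2 and 88 without control replicate 3. BnaC03g02770D and BnaA08g22090D kept their sign but missed the threshold without any one of these 4 libraries (edgeR adjusted p 0.0855 to 0.303 and 0.0998 to 0.157). BnaC06g37480D missed it without control replicate 3, PA23 replicate 2 or PA23 replicate 3 (0.0587 to 0.0831), and BnaA03g38440D without control replicate 2 or PA23 replicate 3 (0.247 and 0.0579). Without control replicate 2 or 3 the log2 fold change was 5.42 or 3.64 for BnaA08g22090D and -2.05 or -3.7 for BnaA03g38440D. DESeq2 gave these 4 genes no adjusted p.

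At 7 d no gene passed the threshold between PA23-treated and control roots (edgeR, 0 of 63551; 4429 genes had an unadjusted p under 0.05). Of the 93 genes higher with PA23 in root at 24 h, 25 (26.9%) had a log2 fold change above 0 at 7 d, with a median of -0.32 over the 93. Of the 77 lower genes, 42 (54.5%) were below 0, with a median of -0.03. Over all 63551 genes the 2 effects were also negatively correlated (Spearman -0.29), so these shares may not be particular to the called genes. Splits of the libraries, given below for abundant genes, did not exclude chance for such a correlation. DESeq2 called 164 genes, or 63 without the libraries under 2 M counts, and limma-voom 0. The edgeR count was 548 without PA23 replicate 1, 81 without control replicate 2 and 1 without PA23 replicate 2. In PA23 replicate 1, 57.6% of low counts were odd, against 18.9% to 33.6% in the other libraries. Leaving it out also gave the highest count for the harvest difference below (2901). Whether its counting plays a part was not tested. All 3 PA23 libraries at 7 d came from one sequencing run and 2 of the 3 controls from the other, so run and treatment are largely confounded here.

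The effect of PA23 in roots differed between the harvests for 243 genes by the test of the difference itself, 94 with a higher and 149 with a lower effect at 7 d (edgeR adjusted p under 0.05). BnaCnng67790D (Cnn_random, 67456660 to 67457745) lay at 8.91 ± 3.51 CPM with PA23 against 0.821 ± 0.338 in controls at 24 h, and at 1.47 ± 1.29 against 3.78 ± 1.66 at 7 d, a difference of log2 effects of -4.46 (SE 0.64, edgeR adjusted p = 0.0161). BnaC03g11290D (C03, 5503441 to 5506546) lay at 5.83 ± 2.34 against 1.09 ± 0.494 CPM at 24 h and at 0.688 ± 0.642 against 2.99 ± 1.72 CPM at 7 d (difference -4.07, SE 0.77, edgeR adjusted p = 0.0396). BnaCnng48510D (Cnn_random, 47825969 to 47829270) was lower with PA23 at 24 h, 1.59 ± 0.453 against 4.93 ± 0.234 CPM, and higher at 7 d, 5.95 ± 2.05 against 1.38 ± 1.31 CPM (difference 3.09, SE 0.56, edgeR adjusted p = 0.0367). BnaA03g38440D, low in all roots at 7 d (0.35 ± 0.336 against 0.226 ± 0.198 CPM), differed by 3.65 (SE 0.75, edgeR adjusted p = 0.048). Scaling changed the balance of directions: 94 of 243 calls (38.7%) were higher at 7 d with TMM and 319 of 566 (56.4%) with RLE size factors. DESeq2 called 1914 genes and limma-voom 2795. With the run as a covariate the count was 16, with no filter 545, among abundant genes alone 1604, and without the libraries under 2 M counts 0 with edgeR (13108 genes had an unadjusted p under 0.05) and 4806 with DESeq2. With all counts halved it was 1397. A replicate block brought it below 243, to a value given with the processing alternatives below. With the 3 closest pairs summed it was 6, and none of the 4 named genes passed (edgeR adjusted p 0.0737 to 0.104). It was 2901 without PA23 7 d replicate 1, 1484 without control 7 d replicate 1, 119 without PA23 7 d replicate 3, 42 without PA23 24 h replicate 1 and 23 without control 24 h replicate 2. It was 11 without control 24 h replicate 3, 10 without control 7 d replicate 3, 6 without PA23 24 h replicate 2 or 3, and 3 without PA23 7 d replicate 2. The named genes kept their sign in each of these 11 fits, but BnaA03g38440D lost its call in 10, BnaCnng48510D in 8, BnaC03g11290D in 7 and BnaCnng67790D in 5. The difference for BnaA03g38440D was 2.63 without control 24 h replicate 2 and 4.27 without control 24 h replicate 3. Without control 7 d replicate 1 it was -2.97 for BnaC03g11290D and -3.86 for BnaCnng67790D.

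**Figure D2:**
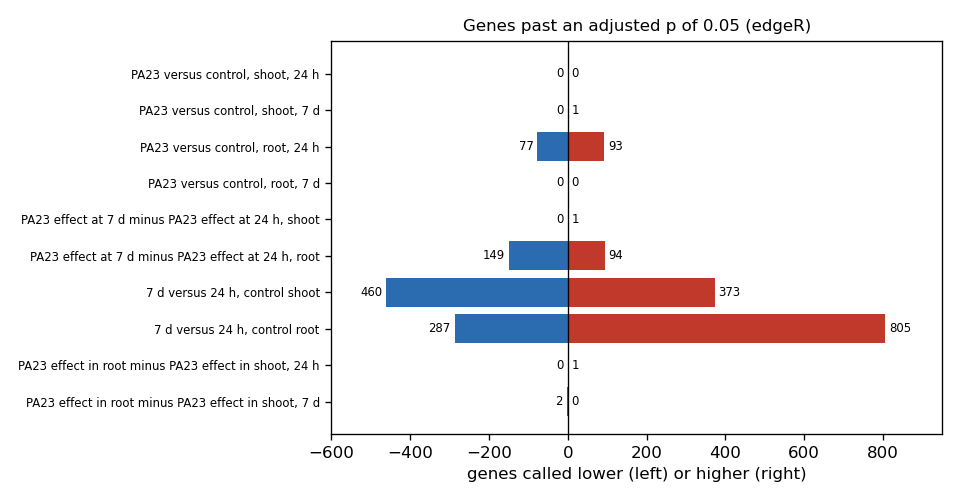
Genes past an adjusted p of 0.05 in each of the 10 contrasts (edgeR), with the number called lower drawn to the left of 0 and the number called higher to the right. In root, 170 genes were called between PA23 and control at 24 h and 0 at 7 d (4429 with an unadjusted p under 0.05; DESeq2 164, limma-voom 0), and control plants of the 2 harvests differed in 833 genes in shoot and 1092 in root.

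In the edgeR fit of all shoot libraries at most 1 gene passed the threshold between PA23-treated and control shoots at either harvest, while other fits called up to 1901. At 24 h none of 56654 genes did (edgeR, with 586 or 1.03% at an unadjusted p under 0.05), DESeq2 called 0 and limma-voom 1. About 5% would reach that unadjusted p if nothing differed. The test may therefore be conservative here, and 0 calls are weak evidence of no effect. Without the libraries under 2 M counts DESeq2 called 28, and edgeR called 1 with no filter and 1 with all counts halved. A single call (1 gene) appeared without control replicate 2, without control replicate 3 or without PA23 replicate 3. At 7 d BnaC01g09700D (C01, 5683764 to 5686252) rose from 16 ± 5.3 CPM in controls to 58.3 ± 2.75 CPM with PA23 (SD, n = 3 each), a log2 fold change of 1.79 (SE 0.25, edgeR adjusted p = 0.00682). The PA23 libraries lay at 55.6 to 61.1 CPM and the controls at 10.8 to 21.4 CPM. DESeq2 and limma-voom called this gene as well (adjusted p = 1.14e-06 and 0.00178). It missed the threshold without control replicate 2 (edgeR adjusted p = 0.136), without PA23 replicate 1 (0.0645), without the libraries under 2 M counts (0.36) and in a fit of the 6 libraries alone (0.136). It also missed it with the 3 closest pairs of libraries summed (edgeR adjusted p = 0.728). PA23 replicates 1 and 3 are one of those pairs (coefficient of variation 2.52%) and control replicates 2 and 3 another (4.81%), and each of these libraries is counted in the n above. The bracketed labels of that PA23 pair, replicates 1 and 3, are 2-3 and 1-3. PA23 replicate 2, with 0.883 M counts, lay between the harvests on the age score described below (-0.48, against 1.66 and 1.64 in replicates 1 and 3). The n of 3, the SD and the adjusted p thus describe a group whose libraries were unlike in the genes that separate the harvests. With the PA23 pair alone summed the edgeR adjusted p was 0.0493. It was the only call of edgeR at 7 d, where DESeq2 made 30 and limma-voom 1901, and DESeq2 made 262 without the libraries under 2 M counts. With no filter edgeR called 14 genes and with all counts halved 20. The edgeR count was 737 without control replicate 1, 3 without PA23 replicate 2, and 0 without control replicate 2 or PA23 replicate 1 (2281 and 1513 genes with an unadjusted p under 0.05). Control replicate 1 had coefficients of variation of 30.3% and 32.4% with control replicates 2 and 3, the highest within any group.

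The PA23 effect in shoot differed between the harvests for 1 gene, BnaC06g27730D (C06, 29117384 to 29119933; edgeR adjusted p = 0.007), chosen after its values were seen. At 7 d it lay at 0.728 ± 0.638 CPM with PA23 and had 0 counts in the 3 controls, which allows up to 0.0275 CPM (3 counts over the group). At 24 h it lay at 0.022 ± 0.0315 CPM with PA23 and at 0.443 ± 0.389 CPM in controls, so it was low throughout. DESeq2 and limma-voom called 0 genes (1042 and 4648 with an unadjusted p under 0.05, and 1472 or 2.6% with edgeR). The edgeR count was 43 without control 7 d replicate 1, 7 without control 24 h replicate 3, 2 without control 24 h replicate 2, and 0 without control 7 d replicate 3, PA23 7 d replicate 1, or PA23 24 h replicate 1 or 2 (1110 to 2541 genes with an unadjusted p under 0.05). It was 0 as well with the 3 closest pairs summed (930 genes), without the libraries under 2 M counts (2314), where DESeq2 called 24, and among abundant genes alone (210).

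The effects of PA23 were also compared between root and shoot. At 24 h BnaA08g04230D (A08, 3574883 to 3579754) differed, by 5.53 on the log2 scale (SE 0.87, edgeR adjusted p = 0.0329), the 1 call among 68002 genes. In roots it had 2 counts in the controls and 0.928 ± 0.462 CPM with PA23, a ratio of 34.4 (95% counting interval 9.47 to 285); in shoots it lay at 11.4 ± 1.24 CPM with PA23 and 10.9 ± 2.66 in controls. The difference was 8.88 without root control replicate 2 and 4.45 without root control replicate 3. The gene missed the threshold in 7 of 11 fits without a library (edgeR adjusted p 0.0784 to 0.243), without the libraries under 2 M counts (0.205), with RLE size factors (0.0703) and with limma-voom (0.0679). At 7 d BnaA02g22460D (A02, 14991772 to 14993317) and BnaA03g25150D (A03, 12162334 to 12162735) differed by -2.98 (SE 0.46) and -2.88 (SE 0.44), both with an edgeR adjusted p of 0.0119. BnaA03g25150D lay at 13.6 ± 5.39 CPM with PA23 against 3.58 ± 0.987 in shoots and at 65.5 ± 14.5 against 106 ± 37 in roots, and BnaA02g22460D at 4.72 ± 3.02 against 1.19 ± 0.247 in shoots and at 8.42 ± 0.371 against 10.9 ± 4.2 in roots. BnaA02g22460D lost its call in 4 and BnaA03g25150D in 5 of 12 fits without a library, and both lost it when only shoot PA23 7 d replicates 1 and 3 were summed (edgeR adjusted p = 0.128). DESeq2 called 8 and 20 genes at 24 h and 7 d, and limma-voom 187 and 4. Without the libraries under 2 M counts DESeq2 called 206 and 161, and edgeR 5 and 1. With all counts halved edgeR called 14 and 7, and among abundant genes alone 0 and 1 (744 genes at 24 h had an unadjusted p under 0.05). At 24 h it called 5 with no filter and 0 with RLE size factors (4050 genes). At 24 h the edgeR count was 36 without shoot control replicate 3, 3 without shoot control replicate 1, and 0 without any one of the 3 shoot PA23 libraries, root control replicate 2, or root PA23 replicate 2 or 3 (2694 to 4524 genes with an unadjusted p under 0.05). At 7 d it was 102 without shoot control replicate 1, 69 without root PA23 replicate 1, 13 without root control replicate 2, 4 without shoot PA23 replicate 2, 1 without root control replicate 3 or root PA23 replicate 3, and 0 without shoot PA23 replicate 1 or 3 or root control replicate 1 (2884 to 3283 genes with an unadjusted p under 0.05). All shoot libraries came from one sequencing run; with the run as a covariate the counts were 10 at 24 h and 0 at 7 d (edgeR; 2789 genes at 7 d had an unadjusted p under 0.05). With the 3 closest pairs summed they were 0 and 0 (edgeR; 3165 and 2380 genes had an unadjusted p under 0.05).

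Across genes, which are not independent replicates, the effects of PA23 in the 4 treatment comparisons had Spearman coefficients of -0.11 to 0.05 in 5 of the 6 pairs of comparisons. In the sixth, root at 24 h against root at 7 d, the coefficient was -0.29 (Pearson -0.1, 63551 genes). It was -0.1 without control 7 d replicate 2, -0.16 without PA23 7 d replicate 2 and -0.41 without control 7 d replicate 1. With no filter it was -0.17, and among abundant genes -0.54. With the run and a replicate block together its sign turned, to a small positive value given with the processing alternatives below.

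In control shoots 833 genes differed between 7 d and 24 h, 373 higher and 460 lower at 7 d (edgeR adjusted p under 0.05). BnaA02g10740D (A02, 5556990 to 5559984) rose from 0.184 ± 0.161 to 34.7 ± 14.2 CPM (log2 fold change 7.03, SE 0.8, edgeR adjusted p = 0.00211). BnaA08g15660D (A08, 13008480 to 13010481) fell from 5.01 ± 1.99 to 0.436 ± 0.66 CPM (log2 fold change -6.07, SE 1.14, edgeR adjusted p = 0.0144). Its 7 d mean rests on 8 counts in all, with 1.2 CPM in replicate 2, a library under 2 M counts, and the ratio of pooled counts was 0.012 (95% counting interval 0.00516 to 0.0237). BnaC02g44900D had 2 counts at 24 h and 920 at 7 d, a ratio of 492 (95% counting interval 136 to 4070), and BnaC03g60820D had 530 counts at 24 h and 2 at 7 d, a ratio of 0.00404 (0.000488 to 0.0147). DESeq2 called 845 genes and limma-voom 2944. With the 3 closest pairs summed, among them 7 d replicates 2 and 3, edgeR called 304. It called 1755 with all counts halved and 216 among abundant genes alone, and DESeq2 called 2595 without the libraries under 2 M counts. The edgeR count was 1946 without 7 d replicate 1, 546 without 7 d replicate 3, 497 without 7 d replicate 2, 333 without 24 h replicate 3 and 224 without 24 h replicate 2. Of the 4 genes, BnaA08g15660D lost its call in 4 of the 6 fits without a library (24 h replicates 2 and 3, 7 d replicates 1 and 3), and it missed the threshold with DESeq2 (log2 fold change -4.21, adjusted p = 0.303) and limma-voom (0.103). The fitted log2 fold change of BnaC02g44900D was 7.7 to 11.3 over these fits (8.6 with all libraries) and that of BnaC03g60820D -10.46 to -6.92 (-7.73).

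In control roots 1092 genes differed between the harvests, 805 higher and 287 lower at 7 d (edgeR adjusted p under 0.05). BnaA05g36800D (A05_random, 2701212 to 2703949) rose from 0.675 ± 0.111 to 29 ± 11.7 CPM (log2 fold change 5.49, SE 0.41, edgeR adjusted p = 5.47e-05). BnaC05g20370D (C05, 13755208 to 13758037) fell from 13.4 ± 5.47 to 0.113 ± 0.136 CPM (log2 fold change -6.49, SE 0.66, edgeR adjusted p = 0.000424). BnaC09g05290D had 4 counts at 24 h, all in 1 library, and 312 at 7 d, a ratio of 63.5 (95% counting interval 24.6 to 235; edgeR adjusted p = 0.00202). Its fitted log2 fold change was 6.41 (SE 0.92), 11.41 without 24 h replicate 3, 5.57 without 24 h replicate 2 and 7.04 without 7 d replicate 1. BnaC08g18680D had 665 counts at 24 h and 7 at 7 d, a ratio of 0.00858 (0.00343 to 0.0178; log2 fold change -6.9, SE 0.6, edgeR adjusted p = 8.25e-05). These 4 genes passed the threshold in each of the 5 fits without a library, and the value for BnaC05g20370D was -5.7 without 7 d replicate 1 and -7.49 without 7 d replicate 2. DESeq2 called 1223 genes and limma-voom 1452. With all counts halved edgeR called 1979 and among abundant genes alone 304, and DESeq2 called 3942 without the libraries under 2 M counts. Without 7 d replicate 1 the edgeR count was 1665, without 7 d replicate 2 it was 569, without 24 h replicate 3 it was 376 and without 24 h replicate 2 it was 297.

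An age score, the log2 ratio of the mean relative level of the genes called higher at 7 d in controls to that of the genes called lower, was computed for each library. The controls chose these genes, so their own separation is not independent evidence. The name refers to harvest time only, since the labels give the same growth time for both harvests. In shoots the score was -2.1 to -1.81 in 24 h controls, -1.35 to -1.34 with PA23 at 24 h and 1.98 to 2.16 in 7 d controls. With PA23 at 7 d, replicates 1 and 3 lay at 1.66 and 1.64 and replicate 2, with 0.883 M counts, at -0.48, so the libraries of this group were unlike each other in the genes that separate the harvests. In roots the score was -2.68 and -2.28 in 24 h controls, -1.01 to -0.86 with PA23 at 24 h, 1.46 to 1.59 in 7 d controls and 0.95 to 1.41 with PA23 at 7 d.

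**Figure D3:**
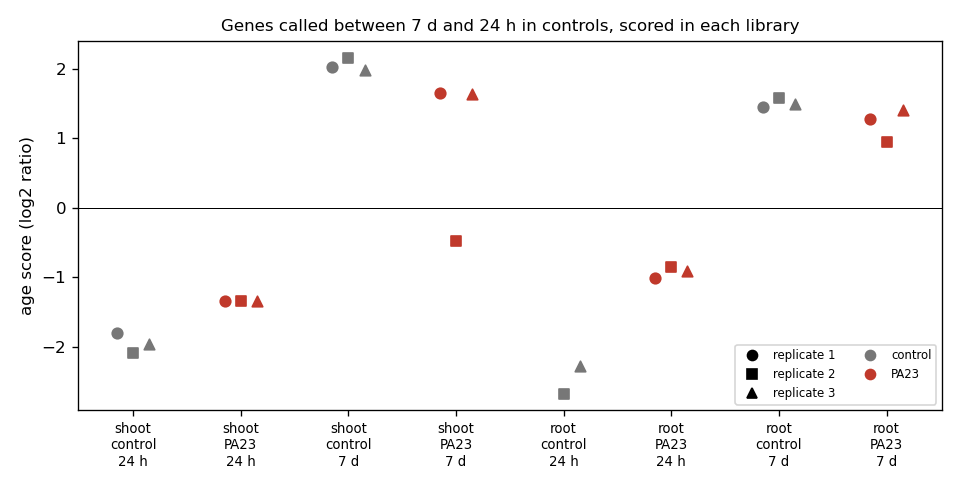
Age score (log2 ratio) of each library, by group, with the marker shape giving the replicate number. Control libraries at 7 d lie above 0 and those at 24 h below it in both tissues; shoot PA23 7 d replicate 2 lies at -0.48, between the harvests.

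Tissue-preferred genes, chosen from the controls of the other harvest, were followed as groups. Each harvest thus had its own lists of 200, which shared 68 shoot-preferred and 51 root-preferred genes. Values at 24 h and 7 d therefore do not follow one set of genes. In shoot at 24 h none of the 200 shoot-preferred genes was called (edgeR 0, and 0 adjusted over the list alone; 586 of all genes had an unadjusted p under 0.05, DESeq2 called 0 and limma-voom 1), with a median log2 fold change of -0.04 (quartiles -0.18 and 0.1; camera adjusted p = 0.379; adjusted p = 0.957 with an estimated correlation). With the preset correlation the list passed without control replicate 2 (median -0.05, camera adjusted p = 0.0117) or PA23 replicate 2 (-0.08, 0.0121), but not with an estimated correlation (adjusted p = 0.69 and 0.689). Its median turned to 0.01 without control replicate 3 and 0.07 without PA23 replicate 3. It was -0.08 without PA23 replicate 1, -0.09 without the libraries under 2 M counts and -0.02 with the 3 closest pairs summed. At 7 d, 0 were called over all genes and 1 adjusted over the list alone (edgeR), and the median was 0.09 (camera adjusted p = 1.09e-05; adjusted p = 0.59 with an estimated correlation). It was -0.08 without control replicate 1, 0.14 without control replicate 2, 0.25 without control replicate 3, 0.06 without PA23 replicate 1, 0.05 without PA23 replicate 3, 0.17 without the libraries under 2 M counts and 0.05 with PA23 replicates 1 and 3 summed. These PA23 libraries and control replicates 2 and 3 are closest pairs (coefficients of variation 2.52% and 4.81%). They enter the summed levels at 7 d as separate libraries. The summed level of the list in shoot at 7 d was 112% ± 3.79 with PA23 and 112% ± 25.9 in controls (SD, n = 3 each; exact permutation test, two-sided, p = 1, where the smallest p possible is 0.1), and at 24 h 104% ± 14.4 and 106% ± 3.61 (exact permutation p = 0.9).

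Of the 200 root-preferred genes in root at 24 h, 4 were called higher and 2 lower with PA23 (edgeR; 18 adjusted over the list alone). The log2 fold change was above 0 for 136 of them, with a median of 0.21 (camera adjusted p = 9.18e-05; adjusted p = 0.514 with an estimated correlation), and 0.13 without PA23 replicate 1. Their summed level was 97.6% ± 1.11 with PA23 (SD, n = 3) and 83.8% ± 2.62 in controls (SD, n = 2). A two-sided exact permutation test gave p = 0.1, the smallest this design allows, and an adjusted p of 0.2 over 4 comparisons. PA23 replicates 2 and 3 are among the 3 closest pairs (coefficient of variation 5.22%) but enter this SD and test as separate libraries. At 7 d a different list of 200 was followed, which shared 51 genes with that at 24 h. Of this list, 149 genes lay below 0, with a median of -0.33 (camera adjusted p = 1.81e-07, and 0.254 with an estimated correlation). No gene of the list was called at 7 d over all genes (edgeR 0, with 4429 of all genes at an unadjusted p under 0.05; DESeq2 164 and limma-voom 0 of all genes), and 7 passed adjusted over the list alone. The summed level was 91.6% ± 14.7 with PA23 and 121% ± 11.7 in controls (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). PA23 replicates 1 and 2 lay at 105% and 94%, and replicate 3, which also held shoot-preferred transcripts at 5.21% of their shoot level, at 75.8%. Without replicate 3 the median was -0.26 (camera adjusted p = 8.22e-06; adjusted p = 0.175 with an estimated correlation), and without replicate 1 it was -0.52. Both medians kept their sign whichever library was left out, but fry, which asks whether a list moves one way, gave adjusted p-values of 0.114 and 0.128.

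Shoot-preferred genes were near the background in roots, and 21 of the 200 on the list of either harvest were measured in the root fit. At 24 h their median log2 fold change was 0.06 while camera's direction was down (adjusted p = 0.847), and the median was -0.19 without control replicate 3, -0.07 without PA23 replicate 1, -0.08 without the libraries under 2 M counts and -0.01 in a fit of the 2 groups alone. It was 0.57 without control replicate 2, 0.17 without PA23 replicate 3, 0.72 with no filter, 0.11 with the 3 closest pairs summed and 0.02 with RLE size factors. With the run and a replicate block together it was -1.11 (camera adjusted p = 0.000201, and 0.343 with an estimated correlation). At 7 d it was 1.34 (camera adjusted p = 0.0353; adjusted p = 0.757 with an estimated correlation), but 0.2 without PA23 replicate 3 (camera adjusted p = 0.131) and 1.05 without control replicate 1 (0.491), and it was 2.95 without control replicate 2, 2.6 without PA23 replicate 1 and 2.18 without PA23 replicate 2. The list also missed the threshold without the libraries under 2 M counts (0.16, 0.0741), with the run as a covariate (1.69, 0.379) and with RLE size factors (1.37, 0.0616). With the run and a replicate block together the median turned to -0.63 (camera adjusted p = 0.47). The median was 0.75 with a filter of 10 counts in 3 libraries (camera adjusted p = 0.0429; adjusted p = 0.676 with an estimated correlation) and 0.95 with no filter (0.000261 and 0.882). In PA23 replicate 3, a library of 1 M counts, the list's summed level was 5.21% of its level in control shoots, against 0.0397% to 0.127% in the other 10 root libraries.

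**Figure D4:**
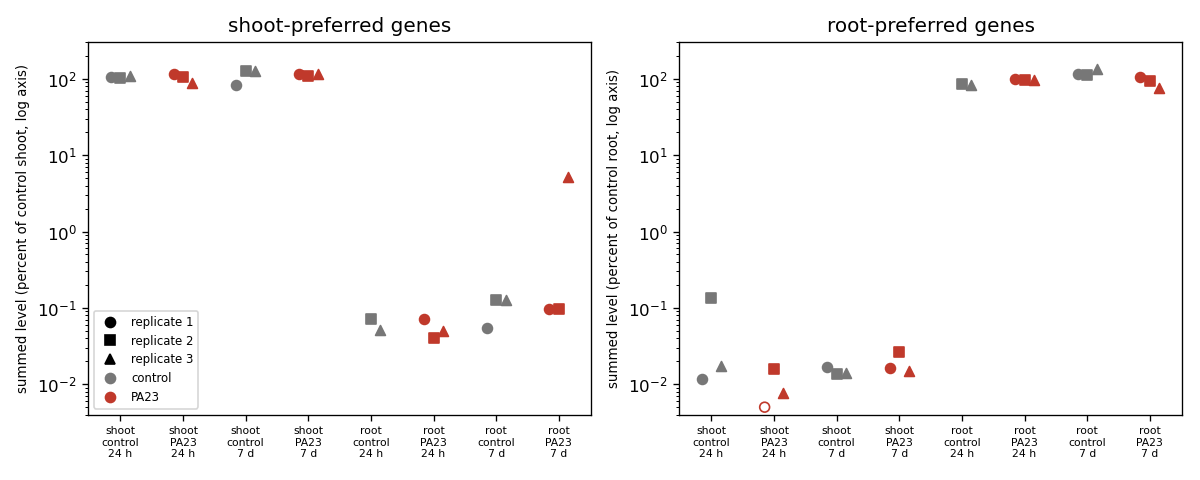
Summed level of 200 shoot-preferred genes (left) and 200 root-preferred genes (right) in each library, as a percentage of control libraries of the preferring tissue, on a log axis. Lists and control libraries are those of the other harvest, so 24 h and 7 d libraries are scored on different lists. One open marker stands for a level of 0 and is drawn at the bottom of the axis; root PA23 7 d replicate 3 lies at 5.21% in the left panel, above the other root libraries.

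The reference table gave another name for 2 genes, and neither passed the threshold in the 8 contrasts within a tissue. KCP1 (BnaA02g32290D) had log2 fold changes with PA23 of -0.16 (SE 0.25) and -0.05 (SE 0.24) in shoot and 0.02 (SE 0.17) and 0.22 (SE 0.17) in root at 24 h and 7 d. TR1 (BnaCnng15100D) had 0.18 (SE 0.34) and -0.21 (SE 0.33) in shoot and 0.16 (SE 0.21) and 0.07 (SE 0.21) in root.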

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

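The tests of shallow sequencing and of mixed material in the shoot library below, and the splits of the differences between harvests in shoot and between tissues at 7 d, were set before their results were seen; the test for a mislabelled library and the tests on close pairs and on shoot transcripts in a root library were chosen after. The rules for the mislabelled library and for the close pairs were revised once their values had been seen; the earlier ones had excluded the first and been met by the second.

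The effect of PA23 differed between the harvests in 243 genes in root and in 1 gene in shoot, by the test of the difference itself. Between root and shoot it differed in 1 gene at 24 h and in 2 genes at 7 d. For the shoot difference, 15 of 40 splits of the libraries called as many genes as the real one (1), and the highest other called 688; for the tissue difference at 7 d, 4 of 24 did (real 2, highest other 502). Chance is therefore not excluded for either, and splits that call 688 or 502 genes point to a structure of the samples that the groups do not describe. The 243 genes in root and the 1 gene at 24 h were not tested by splits. Nor were the 170 genes called for PA23 in root at 24 h or the 1092 called between control root harvests. All involve the root control group of 2 libraries, which did not in itself prevent splits.

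Shoot PA23 7 d replicate 2 lay at an age score of -0.48, between the harvests, while the other PA23 libraries at 7 d lay at 1.66 and 1.64. Shallow sequencing is argued against, since the other 7 d libraries thinned to its depth lay at 1.39 or above. A mislabelled 24 h library stays open. Its score lay above the 24 h PA23 libraries thinned alike (at most -1.13), but that spread is technical only. Its chi-square per gene was 1.36 to 2.57 against the deeper shoot libraries at 24 h and 2.72 to 3.67 against those at 7 d. For the 24 h libraries under 2 M counts these ranges were 1.54 to 3.22 and 3.57 to 5.18 (PA23 replicate 1), and 1.61 to 3.07 and 3.02 to 4.76 (control replicate 1). It thus lay as near to the 24 h shoots as those did, but somewhat nearer to the 7 d shoots. The depths differ, and chi-square grows with depth. A mixture of 24 h and 7 d material may account for the score of -0.48. The genes higher at 7 d gave a 24 h share of 69.7% and the genes lower at 7 d 77.6%. The difference was 7.92 percentage points, where under 20 had been set. An intermediate state of the plant itself stays open too.

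In 3 pairs of replicate libraries the coefficient of variation between them was 2.52% (shoot PA23 7 d replicates 1 and 3), 4.81% (shoot control 7 d replicates 2 and 3) and 5.22% (root PA23 24 h replicates 2 and 3), against 13.1% to 32.4% in the other pairs of the 22. Repeat libraries of one RNA could give this. The 3 pairs were picked as the lowest of the 22, so that 5.22% lies below every other pair follows from that choice. It tests nothing. The bracketed labels, of unstated meaning, are 2-3 and 1-3 in the first pair and 1-2 and 1-3 in the others. The chi-square per gene, computed on counts halved to allow for both mates of a read pair, was 1.54, 1.22 and 2.14. On that scale sampling of read pairs alone gives 1, and independent single counts give less. These pairs thus differed by more than sampling noise. The rule against repeat libraries asked for a coefficient of variation as high as in another pair. The choice of the pairs made that impossible, so this does not decide. With the pairs summed the count in root at 24 h was 26 in place of 170. No biological explanation was tested.

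Root PA23 7 d replicate 3 held shoot-preferred transcripts at 5.21% of their shoot level. A response of roots to PA23 is argued against, since the other PA23 roots at 7 d reached at most 0.0979%, within the range of the controls (up to 0.127%), and so is shallow sequencing, since the other root library under 2 M counts lay at 0.127%. Shoot material or reads in this library may be the source, but 52.5% of 40 abundant shoot-preferred genes lay within 3-fold of one shared percentage, between the limits set for and against it, on 356 counts. It stays open.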

How the results depend on the processing

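The alternatives that left out or summed libraries, halved the counts or kept abundant genes, and all alternatives of the gene lists and of the correlation, were chosen after seeing the data.

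Values are given where a count of called genes moved by more than 1.5 times, a list lost its call or changed sign, or the correlation moved by over 0.1 or changed sign; the cause was not tested unless stated. A filter of 10 counts in 3 libraries did none of these. Among lists that kept call and sign, the median of shoot-preferred genes in root moved by over 0.1, to 0.72 at 24 h with no filter, and at 7 d to 0.75 with that filter, 0.95 with no filter and 1.12 with only the groups compared. With RLE size factors the values were 566 for the harvest difference in root, 0 for the tissue difference at 24 h and a median of 1.37 for shoot-preferred genes in root at 7 d (camera adjusted p = 0.0616). With DESeq2 they were 30 for PA23 in shoot at 7 d, 0 for the harvest difference in shoot, 714 for PA23 in root at 24 h, 164 for PA23 in root at 7 d, 1914 for the harvest difference in root, 8 for the tissue difference at 24 h and 20 for the tissue difference at 7 d. Counts by limma-voom were 1 for PA23 in shoot at 24 h, 1901 for PA23 in shoot at 7 d, 0 for the harvest difference in shoot, 2944 for 7 d against 24 h in shoot, 4755 for PA23 in root at 24 h, 2795 for the harvest difference in root, 187 for the tissue difference at 24 h and 4 for the tissue difference at 7 d. Without a filter the values were 1 for PA23 in shoot at 24 h, 14 for PA23 in shoot at 7 d, 259 for PA23 in root at 24 h, 545 for the harvest difference in root, 5 for the tissue difference at 24 h and a correlation of -0.17 between the root effects. When only the groups compared were fitted they were 5666 for PA23 in root at 24 h and a median of -0.01 for shoot-preferred genes in root at 24 h (camera adjusted p = 0.67). With the sequencing run as a covariate they were 16 for the harvest difference in root, 10 for the tissue difference at 24 h, 0 for the tissue difference at 7 d and a median of 1.69 for shoot-preferred genes in root at 7 d (camera adjusted p = 0.379).

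Without the 6 libraries under 2 M counts edgeR gave 0 for PA23 in shoot at 7 d, 0 for the harvest difference in shoot, 286 for PA23 in root at 24 h, 0 for the harvest difference in root, 5 for the tissue difference at 24 h, 1 for the tissue difference at 7 d, a median of -0.08 for shoot-preferred genes in root at 24 h (camera adjusted p = 0.44) and a median of 0.16 for shoot-preferred genes in root at 7 d (camera adjusted p = 0.0741). On the same libraries DESeq2 gave 28 for PA23 in shoot at 24 h, 262 for PA23 in shoot at 7 d, 24 for the harvest difference in shoot, 2595 for 7 d against 24 h in shoot, 4316 for PA23 in root at 24 h, 63 for PA23 in root at 7 d, 4806 for the harvest difference in root, 3942 for 7 d against 24 h in root, 206 for the tissue difference at 24 h and 161 for the tissue difference at 7 d. With the 3 closest pairs of libraries summed, which leaves fewer samples, the counts were 0 for PA23 in shoot at 7 d, 0 for the harvest difference in shoot, 304 for 7 d against 24 h in shoot, 26 for PA23 in root at 24 h, 6 for the harvest difference in root, 0 for the tissue difference at 24 h and 0 for the tissue difference at 7 d. With only shoot PA23 7 d replicates 1 and 3 summed they were 0 for the tissue difference at 24 h and 0 for the tissue difference at 7 d. With all counts halved they were 1 for PA23 in shoot at 24 h, 20 for PA23 in shoot at 7 d, 1755 for 7 d against 24 h in shoot, 880 for PA23 in root at 24 h, 1397 for the harvest difference in root, 1979 for 7 d against 24 h in root, 14 for the tissue difference at 24 h and 7 for the tissue difference at 7 d. Among genes with an average log2 CPM of 5 or more, which leaves fewer genes, the values were 0 for the harvest difference in shoot, 216 for 7 d against 24 h in shoot, 1604 for the harvest difference in root, 304 for 7 d against 24 h in root, 0 for the tissue difference at 24 h, 1 for the tissue difference at 7 d and a correlation of -0.54 between the root effects. With an estimated correlation camera gave a median of 0.09 for shoot-preferred genes in shoot at 7 d (camera adjusted p = 0.59), a median of 0.21 for root-preferred genes in root at 24 h (camera adjusted p = 0.514), a median of 1.34 for shoot-preferred genes in root at 7 d (camera adjusted p = 0.757) and a median of -0.33 for root-preferred genes in root at 7 d (camera adjusted p = 0.254). Beside the counts of 0, the genes with an unadjusted p under 0.05 numbered 210 to 13108 with edgeR, 1042 with DESeq2 and 4648 with limma-voom.

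Whether replicate numbers pair the libraries is not given in the labels. Over the pairs with the same number, deviations from the group means correlated at -0.37 to 0.1. With groups of 2 or 3 libraries these values cannot decide whether the libraries were paired. With the replicate block the values were 1 for PA23 in shoot at 24 h, 10 for PA23 in shoot at 7 d, 3 for the harvest difference in shoot, 6 for PA23 in root at 24 h, 5 for the harvest difference in root, 25 for the tissue difference at 24 h, 6 for the tissue difference at 7 d and a median of -0.15 for shoot-preferred genes in root at 24 h (camera adjusted p = 0.109). With the run and the replicate block together they were 61 for PA23 in root at 24 h, 9 for PA23 in root at 7 d, a median of -1.11 for shoot-preferred genes in root at 24 h (camera adjusted p = 0.000201, and 0.343 with an estimated correlation), a median of -0.63 for shoot-preferred genes in root at 7 d (camera adjusted p = 0.47) and a correlation of 0.05 between the root effects. With the block alone the median of shoot-preferred genes in root at 7 d was 0.94. The block alone changed the counts of the control harvests by less than 1.5 times.

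With each library left out in turn, counts ranged from 0 to 1 for PA23 in shoot at 24 h, 0 to 737 for PA23 in shoot at 7 d, 15 to 145 for PA23 in root at 24 h, 0 to 548 for PA23 in root at 7 d, 0 to 43 for the harvest difference in shoot, 3 to 2901 for the harvest difference in root, 224 to 1946 for 7 d against 24 h in shoot, 297 to 1665 for 7 d against 24 h in root, 0 to 36 for the tissue difference at 24 h, 0 to 102 for the tissue difference at 7 d. Where 1 library remained in root controls at 24 h it was taken to vary like the other groups. Medians of the lists ranged from -0.08 to 0.07 for shoot-preferred genes in shoot at 24 h, -0.08 to 0.25 for shoot-preferred genes in shoot at 7 d, -0.19 to 0.57 for shoot-preferred genes in root at 24 h, 0.13 to 0.23 for root-preferred genes in root at 24 h, 0.2 to 2.95 for shoot-preferred genes in root at 7 d, -0.52 to -0.26 for root-preferred genes in root at 7 d, and the correlation of the root effects from -0.41 to -0.1. Among them, shoot-preferred genes changed sign in shoot at 24 h without control replicate 3 (0.01) and PA23 replicate 3 (0.07), in shoot at 7 d without control replicate 1 (-0.08), and in root at 24 h without control replicate 3 (-0.19) and PA23 replicate 1 (-0.07). That every change of sign counts was decided after the values were seen. The 20 log2 fold changes of named genes kept their sign in each fit. Depth limits what the libraries of 0.622 to 1.7 M counts can show for low genes.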

Other observations

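The tests of the age score in held-out controls, of the correlation between root effects and of the splits of control shoots were set before their results were seen, although scores and correlations without held-out libraries or splits had been seen; the splits of PA23 against control in shoot at 24 h and 7 d and in root at 7 d were chosen after.

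On the age score, root libraries with PA23 at 24 h lay nearer to the 7 d roots than their controls did. With genes chosen without it, control replicate 2 scored -2.28 against -1.5 to -1.28 with PA23, and control replicate 3 scored -1.97 against -1.15 to -0.83. The smallest gap was 0.78, so a shift of PA23 roots toward the 7 d state by 24 h may be present. This is a hypothesis from 3 against 2 libraries, and PA23 replicates 2 and 3 are among the 3 closest pairs. In shoots, held-out controls scored -1.46, -1.92 and -1.77, and the first of these lay above its PA23 libraries (-1.54 to -1.47) and the last within the range of its own (-1.89 to -1.4), so no such separation was seen there.

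The effects of PA23 in root at 24 h and at 7 d were negatively correlated across 7051 abundant genes (Pearson -0.46). In 8 of 100 paired splits of the libraries the correlation was as far from 0, and the farthest other was 0.62, so chance is not excluded.

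With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. PA23 against control in shoot called 0 genes at 24 h (edgeR, 586 at an unadjusted p under 0.05; DESeq2 0, limma-voom 1; highest other split 51) and 1 at 7 d (highest other 741). The split with 741 genes set control replicate 1 with PA23 replicates 1 and 3 against the rest, which points to a structure of these 6 samples. Control replicate 1 had coefficients of variation of 30.3% and 32.4% with the other controls, the highest within any group. Its chi-square per gene was 83.4 with control replicate 3 but 50.3 and 47.2 with PA23 replicates 1 and 3. Control replicate 3 lay nearer still to those PA23 libraries (30.2 and 27.8). In root at 7 d the real split called 0 (edgeR, 4429 at an unadjusted p under 0.05; DESeq2 164, limma-voom 0; highest other 22), and in control shoots the harvests differed in 833 genes (highest other 1). Where the real split called 0, every split calls at least as many by construction, so nothing was tested there.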
